A study of Mus musculus with 26 samples.

How the data were processed

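The series held 26 samples, of which the 6 RNA-seq libraries had expression files; the 20 chromatin immunoprecipitation and ATAC-seq samples were not analysed here. Per the labels' protocols, RNA was extracted with a column kit and strand-specific poly-A selected libraries were made by a university sequencing core. The deposited values were whole-number read counts per gene, one file per library, without normalization. Each file listed 54146 versioned Ensembl gene identifiers followed by 5 lines with the summary names that HTSeq writes. The submitters' processing notes name the build GRCm38 and, without role or order, FastQC 0.11.7, cutadapt 1.18, STAR 2.6.0c, Bowtie2 2.3.4.3, HTSeq 0.11.0, DESeq2 3.8, SAMtools 1.9, Picard 2.18.19, MACS2 2.1.2 and deepTools 3.1.3. The strand setting used in counting is not given in the sources used here, so overlapping and antisense genes are uncertain.

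The summary lines were left out of library sizes and tests. They took between 24.6% and 26.3% of all entries per library, mostly reads aligned to more than 1 place (18.4% to 20.2%) or to no gene (4.45% to 5.51%). Reads shared by near-identical genes, such as the globin copies, can be lost in this way. Total gene counts were 22561757, 22324838 and 18165046 for MA9+EV replicates 1, 2 and 3 and 18070482, 18530629 and 21531528 for MA9+SETDB1 replicates 1, 2 and 3. A count of 3, the floor used for a gene with no counts, corresponded to between 0.124 and 0.183 CPM in a single library. Folds against an arm without counts were computed as lower bounds from 3 counts over that arm, and where a ratio is given for a gene with 1 to 3 counts in an arm, it is that of normalized counts with an exact 95% binomial interval. These intervals and bounds cover counting error only, since the reads carry no molecular identifiers.

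Gene symbols came from a table of gene identifiers. By versioned identifier 52480 matched, by the stable identifier without version a further 1599, and 67 stayed unmatched, holding 0.0124% of the counts. Coordinates were taken from an NCBI RefSeq annotation of GRCm38.

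Groups were taken from the sample titles, as 3 MA9+EV and 3 MA9+SETDB1 libraries. Genes were filtered with edgeR's filterByExpr by group, scaled with TMM factors, and tested with edgeR's quasi-likelihood F-test (edgeR 4.0.16, limma 3.58.1, R 4.3.3), with Benjamini-Hochberg adjustment over the 12986 tested genes and a threshold of 0.05. CPM values are counts per 1e6 counts of TMM-scaled library size, and standard errors of log2 fold changes were derived from the F statistic. The common biological coefficient of variation was 0.244. The p-values measure the spread between these libraries. The series design calls them biological replicates, but no label says whether they came from separate transductions, and replicates 2 and 3 of each arm were close enough that part of the spread may be technical.

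Before the data were examined, 36 gene lists were fixed for the MLL fusion, H3K9 methylation, myeloid maturation, other blood lineages, cell cycle, signalling and gene families. The 31 lists with at least 5 tested members were tested with limma's camera, a competitive test, with a preset inter-gene correlation of 0.01 and adjustment over the 31 lists. Of these 12 passed, 7 upward and 5 downward. As many lists passed in 7 of the 10 splits of the libraries into 3 against 3, the real split included. With an estimated correlation 3 passed, namely mast cell and basophil, erythroid and eosinophil. With fry, which asks whether a list's genes move in one direction on balance without comparing them with other genes, 21 passed. The list of ribosomal proteins was built from symbols and also took in S6 kinase genes.

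The rule for named genes, also fixed before the data were examined, took Setdb1, Hoxa9 and Meis1. It then took the 10 largest fitted rises and falls and the 5 smallest p-values per direction among called genes with a mean of at least 10 CPM, all 3 libraries of one arm above the other and a symbol other than a predicted gene. For each list it took up to 4 tested members with the smallest p. Genes named outside this rule are said to have been chosen after their values were seen, except tested members of the lists with fewer than 5 of them, which are all reported, and the Y-linked genes. The result for 1 gene that the rule took is not reported here.

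Both arms used the replicate numbers 1 to 3 in their titles. The deviations of same-numbered libraries from their arm means correlated across genes at 0.278, 0.237 and 0.220 for numbers 1, 2 and 3. Replicate 2 of one arm also correlated with replicate 3 of the other (0.257 and 0.215). Deviations within an arm cancel out, so with replicate 1 apart in both arms the values for 2 and 3 largely follow from it. Replicate 2 minus replicate 3 correlated between the arms at -0.105 (genes at 10 CPM or more in both arms). The values thus match the arms by number for replicate 1 only. The block also pairs 2 with 2 and 3 with 3, which they do not bear out. Genes are not independent replicates in these correlations. The fit without the block had been fixed as the main one.

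The gene test was tested on simulated counts for 11288 genes drawn from the MA9+EV means, with 200 changed genes. It recovered 2.5% of 1.5-fold, 56.4% of 2-fold and 90.8% of 4-fold changes, with 5 false calls among 97. In the data 53.5% of the genes were called, and the adjustment is less strict where more genes change. These shares are therefore not those of the real comparison. The list test called 5 of 5 shifted and 0 of 15 unshifted simulated lists. Simulated genes and libraries varied independently, so lists whose genes vary together and the closeness of replicates 2 and 3 were not covered. Alternatives were DESeq2 size factors, upper-quartile factors, no low-count filter, a minimum of 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, robust dispersion, the replicate block, a 1.5-fold threshold (glmTreat), an estimated correlation, fry, and each library left out in turn. Summing replicates 2 and 3, and leaving out replicate 1 of both arms, were added after seeing the data. Figures were drawn with matplotlib 3.10.9.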

Results

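Gene expression was measured in a mouse cell model of acute myeloid leukemia made with MLL-AF9 (MA9), a fusion oncogene found in human leukemias. Lineage-negative bone marrow cells had been transduced with retroviruses carrying MLL-AF9 together with either SETDB1, a methyltransferase for lysine 9 of histone H3, or the empty puromycin-resistance vector (EV). Cultures were kept in medium with IL-3 and SCF for 8 to 12 weeks and selected in puromycin for 3 to 6 weeks. Polyadenylated RNA was sequenced from 3 libraries of MA9+EV and 3 of MA9+SETDB1, which the labels describe as biological replicates. The gene counts per library summed to between 18070482 and 22561757. The comparison asked which genes differed when SETDB1 was overexpressed in these cells, the series being about repression by SETDB1 in this leukemia.

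MA9+SETDB1 libraries had high levels of several mast cell, basophil and erythroid transcripts that were close to absent from MA9+EV, and lower levels of many granule protease and monocyte transcripts that were abundant in MA9+EV. Prss34, a basophil protease, stood at 0.291 ± 0.0401 CPM (counts scaled by library size; mean ± SD, n = 3) in MA9+EV and at 3589 ± 269 CPM in MA9+SETDB1. Elane, the neutrophil elastase gene, stood at 6174 ± 628 CPM in MA9+EV and 4.83 ± 0.36 CPM in MA9+SETDB1. Mef2c, a transcription factor gene known as a target of MLL fusions, had no counts in MA9+SETDB1.

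Setdb1 itself (ENSMUSG00000015697.14, GRCm38 chromosome 3, 95323525 to 95357202) was higher in all 3 MA9+SETDB1 libraries. Its level was 105, 108 and 109 CPM in MA9+EV replicates 1, 2 and 3, against 475, 605 and 607 CPM in MA9+SETDB1 replicates 1, 2 and 3. The fitted log2 fold change was 2.39 (SE 0.13, edgeR adjusted p = 2.42e-05). The labels do not say from which species the introduced coding sequence came, so how much of it the mouse gene count includes is not known. Hoxa9 (ENSMUSG00000038227.15, GRCm38 chromosome 6, 52223097 to 52227370), a homeobox gene known as a target of MLL fusions, fell by 1.22 on the log2 scale (SE 0.11, edgeR adjusted p = 0.000162), from 193 ± 18.9 to 82.6 ± 3.56 CPM. Meis1 (ENSMUSG00000020160.18, GRCm38 chromosome 11, 18880428 to 19019651), which encodes a Hox cofactor, fell by 3.89 (SE 1.05, edgeR adjusted p = 0.0185). Meis1 stood at 8.61 CPM in MA9+SETDB1 replicate 1 but at 0.426 and 0.364 CPM in replicates 2 and 3. Without MA9+EV replicate 2 the Meis1 call was just lost (edgeR adjusted p = 0.0502), and with replicates 2 and 3 of each arm summed it was lost (edgeR adjusted p = 0.0909).

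Of 12986 genes tested with edgeR's quasi-likelihood test, 3554 were higher and 3397 lower in MA9+SETDB1 at a Benjamini-Hochberg adjusted p under 0.05, together 53.5% of the genes. A fitted change of more than 2-fold was found for 2366 of the higher and 1928 of the lower genes, and of more than 16-fold for 820 and 675. No count in any MA9+EV library was recorded for 220 of the higher genes, and none in any MA9+SETDB1 library for 130 of the lower genes. The 2 arms did not overlap for 8392 genes (64.6%), against 10% by chance for 3 independent libraries against 3. Replicates 2 and 3 of each arm were close to each other, so 10% may be too low here.

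**Figure D1:**
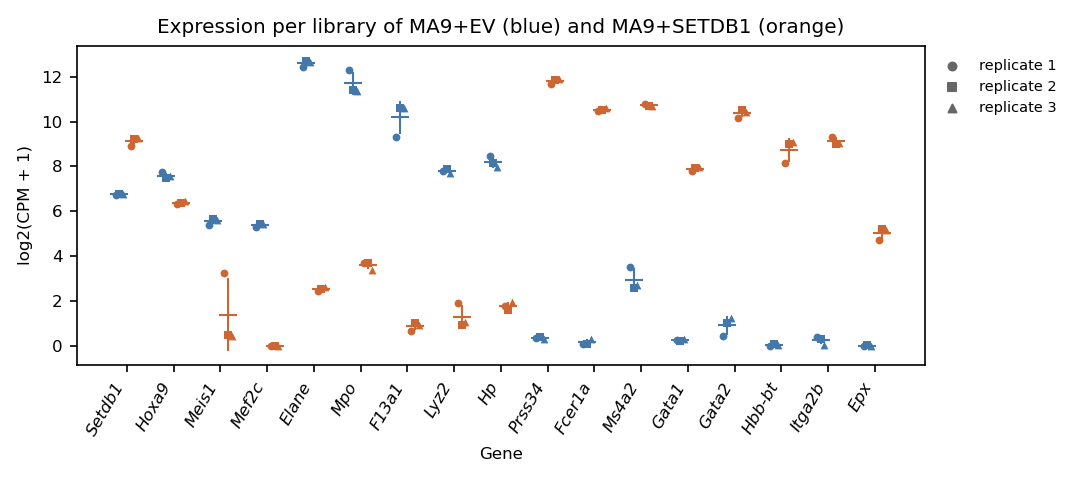
Expression of 17 genes in each library on a log2(CPM + 1) scale, with symbols for replicates 1 to 3, horizontal bars for the mean and vertical bars for the SD of the 3 libraries per arm (MA9+EV blue, MA9+SETDB1 orange). Setdb1 and the mast cell, basophil, erythroid, megakaryocyte and eosinophil genes on the right lie higher in all 3 MA9+SETDB1 libraries, and the genes from Hoxa9 to Hp lie lower in all 3.

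Mast cell and basophil genes rose together, with all 10 tested members higher (camera adjusted p = 1.47e-23, and adjusted p = 0.0129 with an estimated correlation). Fcer1a, the alpha chain of the high-affinity IgE receptor, went from 0.139 ± 0.0976 to 1477 ± 89.1 CPM, and Ms4a2, its beta chain, from 7.11 ± 3.13 to 1686 ± 60.3 CPM. The mast cell chymase gene Cma1 had 1 count in MA9+EV and 6859 in MA9+SETDB1, a ratio of 8731 (95% counting interval 1566 to 344897). All 13 tested erythroid genes rose (camera adjusted p = 1.04e-22, and adjusted p = 0.0396 with an estimated correlation). Gata1, a transcription factor of erythroid, megakaryocyte and mast cells, went from 0.208 ± 0.043 to 238 ± 15.6 CPM, with a log2 fold change of 10.13 (SE 0.17, edgeR adjusted p = 5.49e-07). The erythropoietin receptor gene Epor had 2 counts in MA9+EV and 3446 in MA9+SETDB1. The globin genes Hba-a2 and Hbb-bt reached 63.9 ± 3.6 and 446 ± 144 CPM from 3 counts each over the MA9+EV libraries, but the globin copies are near-identical, so the split of reads among them is uncertain. All 9 eosinophil genes rose (camera adjusted p = 1.80e-07, and adjusted p = 0.0437 with an estimated correlation), among them the peroxidase gene Epx at 32.3 ± 5.8 CPM and the chemokine receptor gene Ccr3, at least 410.3-fold higher than a floor of 3 counts over the MA9+EV arm. Ear1 and Ear2, eosinophil ribonuclease genes that belong to a family of close paralogs, reached 64.4 ± 17.4 and 33.9 ± 12.5 CPM. Of 8 tested megakaryocyte genes, 5 rose and 1 fell (camera adjusted p = 0.000123, but adjusted p = 0.0652 with an estimated correlation). Itga2b, the platelet integrin alpha IIb chain, went from 0.21 ± 0.144 to 565 ± 69.1 CPM, and Rab27b from 2 counts to 238 ± 39.5 CPM. Median log2 fold changes were 12.60, 11.90, 7.93 and 4.81 for the mast cell and basophil, erythroid, eosinophil and megakaryocyte lists. With genes at 0 in one arm set to their bound, the medians were 11.61, 10.57, 5.29 and 3.38.

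Primary granule genes fell, with 6 of 9 tested members lower and 2 higher (camera adjusted p = 6.08e-06, but adjusted p = 0.0545 with an estimated correlation). Prtn3, the proteinase 3 gene, went from 2347 ± 198 to 9.75 ± 1.72 CPM, the myeloperoxidase gene Mpo from 3486 ± 1371 to 11.1 ± 1.41 CPM, and the cathepsin G gene Ctsg from 2182 ± 361 to 42.4 ± 49.5 CPM. Elane fell by 10.32 on the log2 scale (SE 0.23, edgeR adjusted p = 1.02e-06). Of 20 neutrophil differentiation genes, 15 fell and 3 rose (16 and 3 when adjusted over the list alone; camera adjusted p = 0.00502, but adjusted p = 0.738 with an estimated correlation). The haptoglobin gene Hp went from 296 ± 52.1 to 2.48 ± 0.42 CPM and Csf3r, the G-CSF receptor gene, from 53 ± 27.4 to 0.175 ± 0.126 CPM. Ly6g and Itgam, which encode surface proteins of neutrophils and, for Itgam, of other myeloid cells, rose from 10.6 ± 0.919 to 435 ± 124 CPM and from 98.4 ± 2.36 to 405 ± 64.5 CPM. Of 16 tested monocyte and macrophage genes, 9 fell and 4 rose (camera adjusted p = 0.00711, but adjusted p = 0.123 with an estimated correlation). Without MA9+SETDB1 replicate 1 the adjusted p of this list was 0.0996. F13a1, the coagulation factor XIII A gene, went from 1254 ± 529 to 0.862 ± 0.219 CPM, the lysozyme gene Lyz2 from 223 ± 14.4 to 1.58 ± 1.01 CPM, Mpeg1 from 26.3 ± 1.87 to 0.741 ± 0.282 CPM and Ly6c2 from 1818 ± 327 to 291 ± 39.3 CPM.

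**Figure D2:**
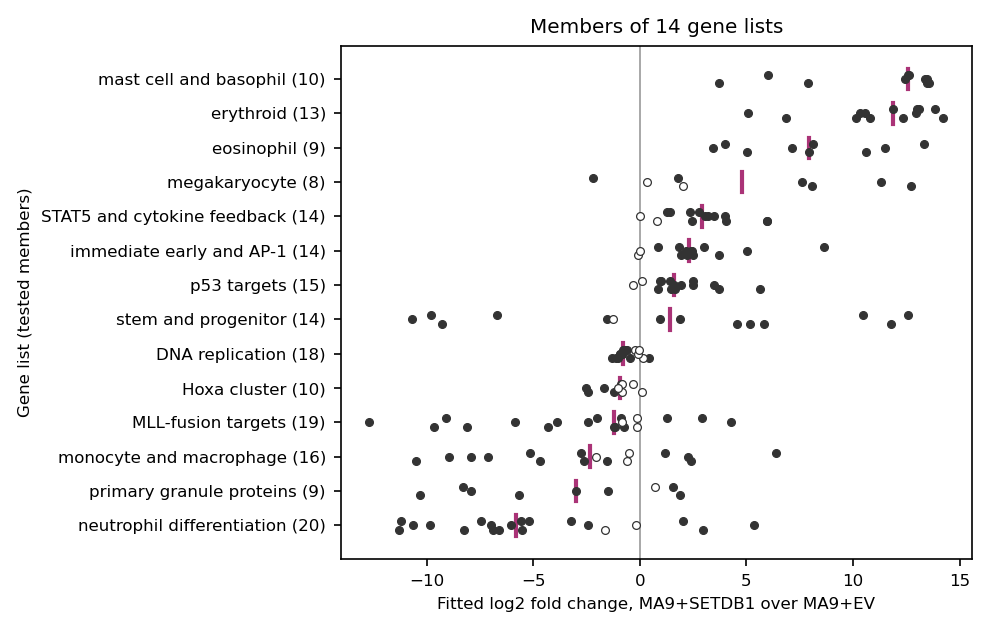
Fitted log2 fold change (MA9+SETDB1 over MA9+EV) of each tested member of 14 gene lists, filled where the edgeR adjusted p was under 0.05, with a vertical bar at the list median. The medians run from -5.79 for neutrophil differentiation to 12.60 for mast cell and basophil genes; the fitted values of genes at 0 in one arm are not bounds.

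Known targets of MLL fusions fell as a group, with 13 of 19 tested members lower and 3 higher (14 and 3 when adjusted over the list alone; camera adjusted p = 0.000281, but adjusted p = 0.0652 with an estimated correlation). Six4 went from 27.6 ± 2.68 to 0.0985 ± 0.128 CPM. Mef2c, which encodes a MADS-box transcription factor, stood at 41 ± 1.97 CPM in MA9+EV and had 0 counts in MA9+SETDB1, at least 730.1-fold lower by a floor of 3 counts over the arm. Runx1 moved the other way, from 64.5 ± 13.1 to 479 ± 21.1 CPM (log2 fold change 2.89, SE 0.17, edgeR adjusted p = 2.68e-05). The counts are per mouse gene and do not give the level of the MLL-AF9 fusion, so whether it differed between the arms is not known. The fall of this list also cannot be told apart from the difference in blood lineage genes between the arms. In the Hoxa cluster, 5 of 10 tested genes fell and none rose, and the list did not pass (camera adjusted p = 0.105, or 0.0491 with the replicate number as a block and 0.0378 without MA9+EV replicate 1; 0.00621 to 0.617 over all alternatives). Hoxa9, Hoxa10, Hoxa3 and Hoxa5 were among the 5, with log2 fold changes of -1.22, -0.87, -1.69 and -2.46. Hoxa5 was uneven, at 42.6 CPM in MA9+EV replicate 1 and 13.3 and 14.6 CPM in replicates 2 and 3. Genes for cofactors of MLL fusions divided, with 4 of 18 higher and 3 lower (3 and 1 when adjusted over the list alone; camera adjusted p = 0.739). Aff1, a fusion partner and elongation factor gene, fell by 4.93 on the log2 scale, from 230.4 ± 15.8 to 7.57 ± 3.41 CPM, whereas its paralog Aff4 went from 117 ± 11.6 to 286 ± 21 CPM. Among 18 genes for other parts of the H3K9 methylation machinery, 4 rose and 4 fell (3 and 4 when adjusted over the list alone; camera adjusted p = 0.637), the methyltransferase genes Ehmt1 and Suv39h2 by log2 fold changes of -0.92 and -1.06. Stem and progenitor genes also divided, with 8 of 14 higher and 5 lower (camera adjusted p = 0.35). Gata2 and Tal1, transcription factor genes active in stem, mast and erythroid cells, went from 0.954 ± 0.531 to 1324 ± 164 CPM and from 0.078 ± 0.0633 to 284 ± 41.6 CPM. Prom1, the CD133 gene, went from 97.6 ± 32.5 to 0.153 ± 0.0784 CPM, and Sox4 had 1 count in MA9+SETDB1 against 2835 in MA9+EV, a ratio of 2227 (95% counting interval 399 to 88001).

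Genes of the STAT5 and cytokine feedback list rose, with 12 of 14 tested members higher (camera adjusted p = 6.08e-06, but adjusted p = 0.413 with an estimated correlation). This list also holds the receptor subunit genes Csf2rb, Csf2rb2 and Il3ra, so its rise is not a measure of signalling. Csf2rb2, a beta subunit gene for the IL-3 receptor with a close paralog in Csf2rb, went from 56.4 ± 7.63 to 3512 ± 1226 CPM, the anti-apoptotic gene Bcl2l1 from 37.4 ± 1.74 to 306 ± 86.4 CPM and the feedback inhibitor gene Socs1 from 5.24 ± 1.65 to 85.6 ± 22.4 CPM. Immediate early genes rose, with 12 of 14 higher (camera adjusted p = 0.000492, but adjusted p = 0.413 with an estimated correlation), including Egr1, from 1.65 ± 1.29 to 667 ± 126 CPM, and Junb, from 32.2 ± 2.9 to 143 ± 18 CPM. Targets of p53 rose, with 13 of 15 higher and none lower (camera adjusted p = 0.000592, but adjusted p = 0.0707 with an estimated correlation). Zmat3 went from 8.13 ± 1.77 to 108 ± 6.99 CPM, Phlda3 from 2.17 ± 0.772 to 24.4 ± 4.62 CPM and Mdm2, which encodes the ubiquitin ligase of p53, from 87.1 ± 4.87 to 175 ± 6.32 CPM. DNA replication genes fell, with 13 of 18 lower and 1 higher (camera adjusted p = 0.0278, but adjusted p = 0.683 with an estimated correlation). Log2 fold changes were -1.13 and -0.95 for the helicase genes Gins2 and Mcm3, -0.62 for the licensing factor gene Cdt1 and -1.31 for the uracil glycosylase gene Ung, with a list median of -0.78.

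Further lists did not pass in the camera test of all 6 libraries. Inflammatory and NF-kB genes had 11 of 17 members higher and 3 lower (camera adjusted p = 0.136, or 0.00135 with the replicate number as a block and 0.0292 without MA9+SETDB1 replicate 1; 3.11e-05 to 0.673 over all alternatives), with the interleukin genes Il1b and Il6 at 1278 ± 632 and 865 ± 603 CPM in MA9+SETDB1 against 0.28 ± 0.229 and 0.0857 ± 0.0368 CPM in MA9+EV. Of 18 tested interferon-stimulated genes, 6 rose and 7 fell (6 and 8 when adjusted over the list alone; camera adjusted p = 0.738), with Oas3 higher at 63.3 ± 6.32 CPM and Ifit2 lower at 0.881 ± 0.0903 CPM. MHC class II genes had 2 of 7 higher and 3 lower (camera adjusted p = 0.953), H2-Oa being higher at 83.4 ± 8.76 CPM and H2-DMa lower at 3.27 ± 1.83 CPM. The direction of this list turned under upper-quartile scaling (adjusted p = 0.993). MHC class I presentation genes had 4 of 10 higher and 6 lower (camera adjusted p = 0.242), the immunoproteasome genes Psmb8 and Psmb9 falling by log2 fold changes of -2.33 and -3.10 while B2m rose from 331 ± 50.2 to 721 ± 38.7 CPM. Myc and ribosome biogenesis genes had 10 of 21 lower and 1 higher (camera adjusted p = 0.36), with Nolc1 at a log2 fold change of -0.68. Of 18 mitosis genes 3 fell (camera adjusted p = 0.293), the survivin gene Birc5 by a log2 fold change of -0.84. Of 18 cholesterol synthesis genes 8 rose (camera adjusted p = 0.35), the synthase genes Lss and Hmgcs1 by log2 fold changes of 1.36 and 1.34. Glycolysis and hypoxia genes had 4 of 19 higher and 5 lower (camera adjusted p = 0.949), with the hexokinase gene Hk2 at a log2 fold change of 0.84 and the kinase gene Pdk1 at -1.89. In this list the median was 0.17 and the mean -0.06.

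Of 320 tested Zfp genes, 49 rose and 77 fell (43 and 70 when adjusted over the list alone; camera adjusted p = 0.433), with Zfp385a going from 2.68 ± 0.655 to 143 ± 21.3 CPM. Clustered protocadherin genes, which share exons, had 4 of 5 tested members lower and 1 higher (camera adjusted p = 0.0675, with 0.000674 to 0.413 over all alternatives). The protocadherin list passed without MA9+EV replicate 1 (0.0191), without MA9+SETDB1 replicate 2 (0.0398), with no low-count filter (0.0254), with replicates 2 and 3 summed (0.0219) and with fry, and Pcdhgc3 went from 16.2 ± 1.69 to 0.0376 ± 0.0329 CPM. Of 5 tested germline genes, 4 rose and 1 fell (camera adjusted p = 0.433), with Dazl at 2.09 ± 0.723 CPM in MA9+SETDB1 and Tdrkh falling from 7.71 ± 2.48 to 0.395 ± 0.152 CPM. Imprinted genes had 3 of 8 higher and 3 lower (4 and 3 when adjusted over the list alone; camera adjusted p = 0.664), Phlda2 being at least 179-fold higher and Igf2r lower by a log2 fold change of -0.86. Replication-dependent histone genes had 9 of 12 higher (camera adjusted p = 0.0735, or 0.0491 with the replicate number as a block, 0.0159 without MA9+EV replicate 1 and 0.0464 without MA9+SETDB1 replicate 2; 0.00102 to 0.516 over all alternatives), with Hist1h1c going from 13.5 ± 5.65 to 157 ± 44.7 CPM. Their transcripts mostly lack poly-A tails, so poly-A libraries sample them poorly. Of 94 genes with ribosomal protein symbols, 11 rose and 5 fell (2 and 1 when adjusted over the list alone; camera adjusted p = 0.668). The 3 with the smallest p encode S6 kinases rather than ribosomal proteins, namely Rps6kl1, Rps6ka4 and Rps6ka5, with log2 fold changes of 6.76, 0.58 and -0.94. Of 13 mitochondrial transcripts 3 fell (0 higher and 1 lower when adjusted over the list alone; camera adjusted p = 0.397), with mt-Nd6 at a log2 fold change of -1.42. For every list whose pair of counts is not given, adjustment over the list alone gave the same counts as over all genes.

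B cell, T and NK cell, dendritic cell, stromal and sex-linked lists had fewer than 5 tested members and no list test. Among B cell genes, Igll1 was at least 40.6-fold lower and Cd79b stood at 2.03 ± 1.68 and 2.83 ± 0.474 CPM (edgeR adjusted p = 0.513). Of T and NK cell genes, Il7r and Nkg7 were higher, at 3.47 ± 1.16 and 36.4 ± 11.9 CPM in MA9+SETDB1, and Lck lower, at 3.48 ± 1.14 CPM. Of dendritic cell genes, Itgax and Zbtb46 were higher and Tcf4 lower, the last going from 44.9 ± 7.13 to 1.59 ± 0.811 CPM. Among stromal genes, Pdgfrb went from 0.0612 ± 0.0343 to 54.1 ± 24.9 CPM and Lepr from 1.16 ± 0.186 to 0.321 ± 0.264 CPM. Xist was present in all 6 libraries (763 ± 119 and 508 ± 326 CPM, edgeR adjusted p = 0.271), and the Y-linked genes Kdm5d, Uty, Ddx3y and Eif2s3y had 0 counts in MA9+EV and at most 2 each in MA9+SETDB1.

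The genes with the largest fitted rises were Add2, Cd226, Gpc4, Cd200r3, Podxl, Rhag, Maob, Il1rl1, Btn1a1 and Hba-a1. Rhag, an erythroid membrane protein gene, had no counts in MA9+EV and was at least 2713-fold higher, as was Add2, an erythroid cytoskeleton gene, at least 5459-fold. Il1rl1, the IL-33 receptor gene of mast cells and basophils, went from 0.0688 ± 0.119 to 1202 ± 66.3 CPM and Cd200r3, a basophil and mast cell receptor gene, from 3 counts to 1195 ± 389 CPM. Btn1a1 was uneven, at 1.85 CPM in MA9+SETDB1 replicate 1 and 145 and 131 CPM in replicates 2 and 3, and its call was lost with limma-voom (adjusted p = 0.0945). The largest fitted falls were those of Mef2c, Hnmt, Greb1, Cd28, P2rx3, Nrp2, Camp, Chil3, Thbs1 and Sox4. Thbs1, the thrombospondin 1 gene, went from 5722 ± 2776 to 2.98 ± 0.316 CPM and Nrp2 from 129 ± 4.8 to 0.0389 ± 0.0338 CPM. Chil3, a chitinase-like gene of myeloid cells, stood at 886 CPM in MA9+EV replicate 1 and at 50 and 45.5 CPM in replicates 2 and 3, and its call was lost with limma-voom (adjusted p = 0.0652). By smallest p, Gata1, Prss34, Ikzf2, Hba-a2 and Erv3 led the higher genes and Tfec, Snx9, Sgpp1, Trem3 and Rnf213 the lower ones. Ikzf2, which encodes the transcription factor Helios, went from 0.072 ± 0.0187 to 252 ± 27.1 CPM, and Tfec, of the MiT transcription factor family, from 392 ± 6.95 to 0.297 ± 0.0702 CPM.

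**Figure D3:**
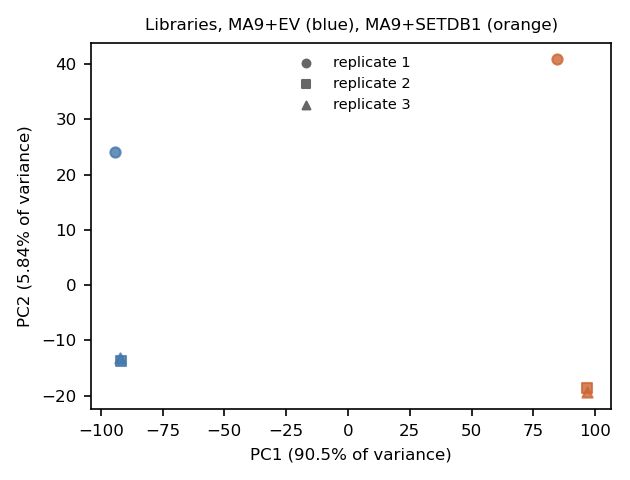
Principal components of log2(CPM + 1) over the 12986 tested genes, with each library as 1 point (MA9+EV blue, MA9+SETDB1 orange; circle, square and triangle for replicates 1, 2 and 3). The first component, 90.5% of the variance, separates the arms, and the second, 5.84%, separates replicate 1 of each arm from replicates 2 and 3, whose points nearly coincide.

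Replicates 2 and 3 of each arm were close to each other, and replicate 1 stood apart. The coefficient of variation beyond counting noise was 0.0417 between MA9+EV replicates 2 and 3 and 0.0368 between MA9+SETDB1 replicates 2 and 3, against 0.301 and 0.297 for MA9+EV replicate 1 and 0.352 and 0.36 for MA9+SETDB1 replicate 1. The close pairs still differed by more than sampling noise, with chi-square values of 4.03 and 2.99 per degree of freedom, and were counted as separate samples. These values do not show that the libraries of a pair came from separate cultures. When replicates 2 and 3 of each arm were summed, 2292 genes were higher and 1928 lower. When replicate 1 of both arms was left out, so that only the close pairs remained, 5314 were higher and 5285 lower.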

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

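Summing replicates 2 and 3 and leaving out both replicate 1 libraries were chosen after the data were seen. Setdb1 kept its direction and call under all settings in which it was tested, with log2 fold changes of 2.32 to 2.51. No gene called by the test of all 6 libraries changed sign under any alternative. The counts of 3554 higher and 3397 lower genes stayed within 1.5 times under both other scalings, both other filters, DESeq2, limma-voom, robust dispersion and the block, and under leaving out 1 library ran from 2992 to 4231 and from 2727 to 4063. They became 2313 and 1924 with a threshold of 1.5-fold, as a stricter test must give, and 2292 and 1928 with replicates 2 and 3 summed, where fewer samples remain and 56.7% of the calls were kept. Lower genes became 5285 without both replicate 1 libraries. Lists past the threshold numbered 12, against 3 with an estimated correlation and 21 with fry. The MLL-fusion target, neutrophil and monocyte lists had adjusted p = 0.0652, 0.738 and 0.123 with an estimated correlation, and the stem and progenitor list 0.00621 with fry. The estimated correlations were -0.00195 for MLL-fusion targets, 0.752 for neutrophil and -0.00989 for monocyte genes. A correlation above the preset 0.01 could thus weaken the neutrophil list, but argues against that cause for the MLL-fusion target and monocyte lists. Other lists that lost their call had estimated correlations of -0.0802 (primary granule), -0.00914 (p53 targets) and 0.00468 (megakaryocyte), all under the preset. Those of the DNA replication, immediate early and STAT5 lists were 0.347, 0.254 and 0.568. The mast cell and basophil list, at -0.0481, went from camera adjusted p = 1.47e-23 to 0.0129. A call lost with an estimated correlation is thus not by itself a sign that genes varied together. What else changed these values was not tested. The monocyte list ran from 0.00286 to 0.0996 when 1 library was left out, the highest without MA9+SETDB1 replicate 1. The MLL-fusion target list ran from 5.52e-05 to 0.00713. Lists without a call turned direction as follows, and the cause was not tested. MHC class II turned with upper-quartile factors (0.993), a minimum of 1 CPM (0.839) and fry (0.891). Interferon-stimulated genes turned with the block (0.959) and without both replicate 1 libraries (0.866), and glycolysis genes in the same settings (0.959 and 0.529). With 1 library left out, the adjusted p ranges were 0.582 to 0.95 for the MLL-fusion cofactors, 0.658 to 0.985 for glycolysis, 0.459 to 0.977 for interferon-stimulated and 0.604 to 0.977 for imprinted genes, each with a turn. With the replicate number as a block, a pairing not shown for numbers 2 and 3, 3791 genes were higher and 3761 lower. The block gave 15 lists, adding the Hoxa cluster, inflammatory and histone lists, and changed no other list call; among named genes it added mt-Cytb alone. Of 150 named genes, 14 lost their call with replicates 2 and 3 summed, 3 with limma-voom and at most 3 when 1 library was left out. Depth limits genes with few counts. The simulation recovered few changes of 1.5-fold, though with a far smaller share of changed genes than in the data.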

Other observations

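Several regulators outside the fixed lists or their named members also differed; they were chosen after their values were seen. The cyclin-dependent kinase inhibitor genes Cdkn2a, Cdkn2b and Cdkn2c went from 2.12 ± 0.78 to 353 ± 173 CPM, from 0.23 ± 0.159 to 105 ± 59 CPM and from 5.85 ± 5.8 to 74.7 ± 12.1 CPM. Cdkn1a, Cdkn1b and Cdkn2d were higher too, by log2 fold changes of 2.49, 1.54 and 0.92, while Cdkn1c was lower by -3.36 (edgeR adjusted p between 0.000104 and 0.00835 over the 7 genes). Gfi1b, a repressor of erythroid and megakaryocyte cells, went from 0.0749 ± 0.0659 to 76 ± 34.8 CPM and its paralog Gfi1 the other way, from 402 ± 90.2 to 6.99 ± 6.26 CPM. Irf8, a monocyte and dendritic cell factor, had 1 count in MA9+SETDB1 against 825 in MA9+EV. Spi1, which encodes PU.1, stood at 195 ± 24.3 and 209 ± 10.5 CPM (edgeR adjusted p = 0.501).

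The cytokine genes Il13 and Il4 stood at 38.2 ± 24.4 and 69.4 ± 23.9 CPM in MA9+SETDB1, against 0 counts of either in MA9+EV. The hepatocyte growth factor gene Hgf went from 5.67 ± 0.882 to 759 ± 105 CPM. Kit, the SCF receptor gene that mast cells usually express, went from 114 ± 3.01 to 1.07 ± 1.22 CPM, whereas Csf2rb went from 357 ± 26 to 4019 ± 1249 CPM. The DNA methyltransferase gene Dnmt3b went from 13.5 ± 0.447 to 0.356 ± 0.13 CPM, and Dnmt3a from 11.7 ± 0.854 to 33.1 ± 9.61 CPM. These genes too were chosen after their values were seen.

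The tests in the next 3 paragraphs were chosen after the patterns were seen. The first pattern is the low level of many granule and monocyte genes beside high mast cell, basophil and erythroid genes in MA9+SETDB1. The primary granule, neutrophil and monocyte lists had 35 tested members at 10 CPM or more in MA9+EV, of which 25 fell and 7 rose. Their median level in MA9+SETDB1 was 2.75% of that in MA9+EV (quartiles 0.372% and 76%). An unchanged remainder of MA9+EV-like cells would keep each gene at or above its own share of the RNA. The lower quartile thus puts that share at about 0.372% or less. This argues against cells of another type added to a large unchanged remainder. A remainder below that share stays open, since the share of cells like those of MA9+EV is not known. A library swapped between the arms is argued against by Setdb1, whose lowest MA9+SETDB1 library stood 4.36 times above the highest MA9+EV library. A candidate explanation is that the MA9+SETDB1 cultures came to consist of cells of another blood lineage, but whether such cells changed identity or grew out from different founder cells over 8 to 12 weeks was not tested, and no value in the count tables separates a direct effect of SETDB1 from either.

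The second pattern is that replicate 1 stood apart from replicates 2 and 3 in both arms. Depth does not account for it, since the coefficient of variation between MA9+EV replicates 1 and 2, of like depth, was 7.22 times that between replicates 2 and 3, of unlike depth. A library deposited 2 times is argued against by a chi-square of at least 2.99 per degree of freedom between replicates 2 and 3. Over 7879 genes at 10 CPM or more in both arms, the difference of replicate 1 from replicates 2 and 3 correlated between the arms at r = 0.414, against -0.105 for replicate 2 minus replicate 3, which is consistent with a culture or handling difference of replicate 1 that both arms shared. Of 14 tested amino acid and ATF4 response genes, a list chosen after several of them had been seen, 13 were lower in replicate 1 than in replicates 2 and 3 in both arms, with median log2 differences of -1.18 in MA9+EV and -1.06 in MA9+SETDB1.

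The third pattern lies on distal chromosome 2, where, from 110 Mb, a start chosen on these values, to the end (GRCm38), the median log2 fold change of 326 genes at 10 CPM or more in both arms was 0.44, against -0.05 for 319 genes before it and -0.04 on the other chromosomes pooled, and each of the 3 MA9+SETDB1 libraries showed it (medians of 0.49, 0.51 and 0.48 relative to the MA9+EV mean, less the median of the other chromosomes). Chance clustering of changed genes is argued against by a shuffle of gene order, in which no 100-gene window reached the observed maximum of 0.55 (highest 0.34; permutation p = 0.001, the smallest that 1000 shuffles can give), though shuffling ignores neighbours that are regulated together. Of the other chromosomes, 16 departed most, with a median of -0.22 over 244 genes, and the lowest window, on chromosome 3, had a median of -0.27 (permutation p = 0.0719). A median over 326 genes cannot be moved far by a few strongly changed genes, so the median of 0.44 could not test that explanation. The lower quartile of the region, 0.08, also lay above the median of the other chromosomes. The shift was thus spread over most genes of the region, though its start was chosen on these values. All 8 bins of 10 Mb with 20 or more genes lay above the rest of the chromosome (medians 0.17 to 0.57), but a start chosen on these values gives that as well, and the 2 bins before it had medians of 0.10 and 0.14, so an extra copy of the region in MA9+SETDB1 cells, loss of a copy in MA9+EV cells and regulation over the region all stay open.

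Comparing the real split with the others was fixed before the data were examined. The 6 libraries make 10 splits of 3 against 3, too few for a share under 0.05. With edgeR, the real split gave 3554 higher and 3397 lower genes as the 1 of 10 with as many in either case, and the highest of the other splits gave 0, with 1 to 317 genes at an unadjusted p under 0.05; other tools were not run on the splits. For the gene lists, 7 of the 10 splits passed as many as the real 12, the highest being 18. Of the 10, 4 part all 3 same-numbered pairs; beside the real one these gave 0 genes with edgeR, 1, 1 and 220 at an unadjusted p under 0.05, and 16, 18 and 1 lists. In each split other than the real one, a side holds 2 libraries of one arm and 1 of the other. The difference between the arms then adds to the spread within each side. Few genes could be called in such splits, so their 0 calls are no measure of chance. Each side also keeps part of the difference between the arms, so the lists passed there are no measure of chance either. The number of lists passed thus does not set the real split apart.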
